A study of Arabidopsis thaliana with 4 samples.

How the data were processed

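RNA of 4 seedling pools was labelled with biotin by an Affymetrix 3' IVT kit, per the labels' protocols, and read on expression arrays, with 2 pools of the RKD4-inducible line and 2 of the control line. Plants grew at 23 °C with 16 h of light and 8 h of dark. The submitters' processing notes name GCOS, Affymetrix's operating software, and its version and settings are not given in the sources used here. The deposited values are intensity on a linear scale, a signal per probe set summarised by the authors before deposit. Their 2% trimmed mean was close to 500.05 on every array, so the authors' scaling was kept. No detection calls were used here, so no probe set was called present or absent. The values of 22810 probe sets were used after leaving out 64 AFFX control probe sets, which gives 22746 tested.

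From these values log2(signal + 32.4) was computed, where 32.4 is the 25th percentile of all values of the tested probe sets. Between 24.2% and 25.8% of probe sets per array lay under it. A linear model with the group as its only term was fitted to all 4 arrays with limma 3.58.1 in R 4.3.3, with variances moderated along the mean signal. Two-sided p-values were adjusted by Benjamini-Hochberg over all probe sets at a threshold of 0.05. The design leaves 2 residual degrees of freedom and the moderation added 4.12. An exact two-sided permutation test of 2 against 2 arrays cannot go below p = 0.333, so none was run for single genes. The labels call the arrays biological replicates but do not say whether the pools were grown apart, so p-values measure the spread between these pools only. The fitting step was tested on simulated data with the comparison's 22746 probe sets: 84 of 100 probe sets changed 2-fold and 100 of 100 changed 4-fold were recovered. It made 14 false calls, 7.07% of its calls, above the nominal share. Only those probe sets were changed in the simulation, against 4954 called in the data. Its noise was independent and normal, with the moderated variances, so these rates need not hold for the data.

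Probe sets were named through the platform annotation given, updated by gene identifier to the TAIR10.1 gene table. Of the tested probe sets 13513 have 1 gene there, 503 have several and 8730 have none, and 13436 of the 13513 matched the gene table. No gene was named from a probe set with several, and an unnamed probe set may still read a gene. The 3 probe sets that fell at least 8-fold have no gene in this table. Named probe sets changed in 19.8% of cases and the others in 24.7%. A gene stands for its probe set with the highest mean, and none of 146 genes with more than 1 probe set had calls in opposite directions. No genome build is named for the array, so no coordinates are given. The RKD4 test fixed beforehand was not run, since none of the 5 RKD genes has a probe set in the table.

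Genes were named by a rule fixed before the data were examined: RKD4, the 12 largest rises and 12 largest falls among probe sets with 1 gene, an adjusted p under 0.05 and groups that do not overlap, then up to 4 members of each of 22 gene lists with the largest absolute change. Genes with a symbol, ranked to 16 in each direction, and families by symbol prefix with at least 5 genes were added after the values were seen. A result for 1 family is not reported here. Lists without a measured gene were the RKD, NIN-like, D-type cyclin, gibberellin, nitrate and heat shock lists. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, and with fry for a shift in 1 direction and for change in either direction. Alternatives were quantile normalization, median centring, pseudocounts at the 10th percentile and of 1, a filter at the 30th percentile of mean signal, no variance trend, the replicate number as a block, other thresholds and leaving out each array. A fit with an array left out has fewer residual degrees of freedom, so a call lost there need not mean dependence on that array. Alternatives added after seeing the data were 1 probe set per gene and stricter definitions of neighbouring genes. Others were a family background of all named genes, tried before the main one, and leaving out probe sets over 2-fold apart between the control arrays.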

Results

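Gene expression was measured on 4 Affymetrix arrays in *Arabidopsis thaliana* seedlings of the Col-0 ecotype. RKD4 is a plant transcription factor of the RWP-RK family that acts in the early embryo. One line carried RKD4 behind a promoter that the chimeric activator GVG switches on when dexamethasone is given, and the control line carried GVG alone. Both lines received 1 µM dexamethasone for 24 h from day 2 after germination and were harvested on day 3. Each group held 2 arrays, and each array read a separate pool of 60 seedlings. The median signal per array lay between 175 and 185, and the small number of arrays limits the precision of every value below. Values are log2 changes of RKD4-induced over control seedlings ± SE, with n = 2 arrays per group, on the log2(signal + 32.4) scale, which understates the change of weak genes.

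The comparison asks which transcripts differ between the RKD4-inducible and the control line after a day of dexamethasone. No array without dexamethasone is among the samples. A difference between the lines from another source therefore cannot be told apart from an effect of RKD4. Among probe sets with 1 assigned gene, the largest rises were of genes close to background in control seedlings. AT1G71470 rose by 7.43 ± 0.11, from a mean signal of 3.43 ± 1.17 (SD) in control to 6170 ± 217 in induced seedlings. AT3G62320 rose by 6.86 ± 0.13 and AT5G48350 by 6.37 ± 0.14. EC1.5 (AT5G64720), which encodes a small cysteine-rich protein secreted by the egg cell, rose by 6.07 ± 0.14, from 1.46 ± 0.23 to 2254 ± 209. AT4G00920 rose by 5.84 ± 0.15, AT3G54310 by 5.66 ± 0.15, AT5G37140 by 5.61 ± 0.27 and AT2G01790 by 5.28 ± 0.14. AT1G56040 (5.17 ± 0.15), AT5G01150 (5.11 ± 0.16), AT4G03630 (4.73 ± 0.15) and AT5G32460 (4.69 ± 0.16) completed the 12 largest rises on this scale. Control signals of these 12 genes lay between 0.772 and 18.5 on single arrays, all under the pseudocount, and induced signals between 807 and 6324. Their adjusted p was at most 0.000247 (limma, Benjamini-Hochberg). The sizes and order of these rises depend on the pseudocount: with a pseudocount of 1 all kept their calls, and those that grew by over 1.5 times were EC1.5 (9.84), AT4G00920 (9.68), AT5G37140 (8.44), AT5G01150 (8.28), AT5G32460 (8.07), AT1G56040 (7.98) and AT4G03630 (7.54).

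Of 13356 genes 1557 carry a symbol in the reference table, and of 143 genes at least 4-fold higher 127 were named by locus alone. Those with a symbol were also ranked, a choice made after the values were seen. ARR15 (AT1G74890), a type-A response regulator of cytokinin signalling, rose by 4.61 ± 0.20, from 43.6 ± 19.2 to 1797 ± 224. GH9A3, a membrane-bound endoglucanase, rose by 4.21 ± 0.19. The chromatin remodelling genes CHR34 and CHR40 rose by 3.99 ± 0.22 and 2.62 ± 0.17. ATYKT62, a SNARE of vesicle traffic, rose by 3.12 ± 0.22 and the cell wall invertase gene cwINV6 by 2.85 ± 0.14. SGT1A, a co-chaperone of disease resistance proteins, was already well expressed and rose by 2.61 ± 0.13, from 467 ± 75.2 to 3001 ± 19.7. RAPTOR2, a partner of the TOR kinase, rose by 2.51 ± 0.13, CF9 by 2.45 ± 0.22 and the tetraspanin gene TET9 by 2.38 ± 0.20. UGT74F1, a salicylic acid glucosyltransferase, rose by 2.35 ± 0.23. The MADS-box genes AGL18 and AGL65 rose by 2.27 ± 0.12 and 2.25 ± 0.17. TRI, a tropinone reductase gene, rose by 2.22 ± 0.14, and EMS1, a receptor kinase of anther development, by 2.06 ± 0.13. With a pseudocount of 1 ATYKT62 lay at 6.66 and CHR34 at 6.18.

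**Figure D1:**
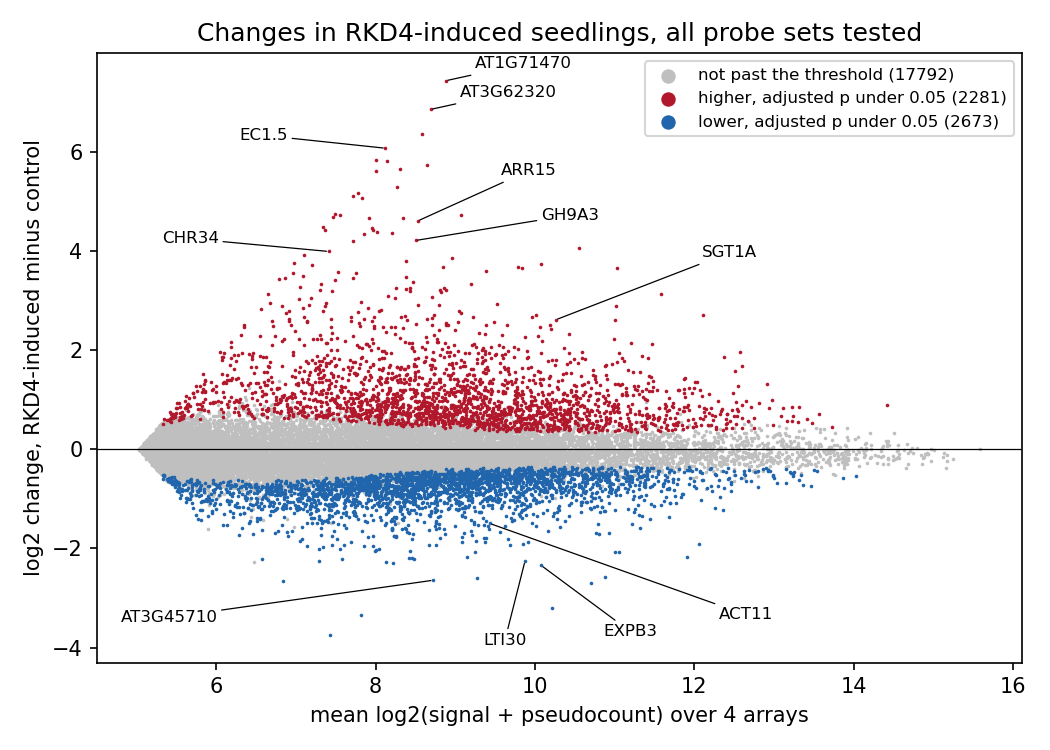
Log2 change of RKD4-induced over control seedlings (vertical axis) against the mean log2(signal + 32.4) over 4 arrays (horizontal axis), with a point per probe set tested. Red points mark the 2281 probe sets that rose, blue points the 2673 that fell and grey points the rest, and the rises reach much larger sizes than the falls.

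Among probe sets with 1 assigned gene, the largest falls were smaller than the largest rises. The 3 probe sets that fell at least 8-fold have no gene in the table used and are not listed here. AT5G62210 fell by 2.65 ± 0.40, though its control arrays lay far apart (388 in replicate 1 and 164 in replicate 2). AT3G45710 fell by 2.64 ± 0.14. EXPB3, a beta-expansin that loosens cell walls, fell by 2.34 ± 0.15, from 2404 ± 53.5 (SD) to 452 ± 92.4. AT4G33550 fell by 2.28 ± 0.15 and AT4G39675 fell by 2.28 ± 0.23. LTI30, a dehydrin gene of cold and drought, fell by 2.26 ± 0.11, from 2027 ± 205 to 396 ± 2.04. The expansin-like gene EXLB1 fell by 2.24 ± 0.26 and AT1G33055 fell by 2.22 ± 0.21. AT4G30460 fell from 718 ± 11.5 to 132 ± 29.7. SP1L4, a relative of the microtubule protein SPIRAL1, fell from 702 ± 8.39 to 128 ± 13.3. AT3G27400 fell by 1.98 ± 0.17 and AT3G46700 fell by 1.94 ± 0.22. The adjusted p of these 12 genes was at most 0.00715 (limma, Benjamini-Hochberg). Without RKD4-induced replicate 2, AT5G62210 lay at -2.32 with an adjusted p of 0.0671, and it was the only one of the 24 genes to lose its call under any setting tried. With a pseudocount of 1 it lay at -4.48 and AT1G33055 at -3.89.

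Further genes with a symbol that fell were again ranked after the values were seen. EXPB1, another beta-expansin, fell by 1.80 ± 0.21, TET12 fell by 1.74 ± 0.25 and the glucosyltransferase gene UGT84A1 fell by 1.66 ± 0.17. UPB1, a bHLH regulator of root growth, fell by 1.58 ± 0.19. LigB fell by 1.52 ± 0.11, GSTU28 fell by 1.52 ± 0.14 and ARLA1B fell by 1.51 ± 0.16. The actin gene ACT11 fell from 1130 ± 66.8 (SD) to 379 ± 6.10. The ubiquitin ligase gene PUB19 fell by 1.53 ± 0.26, the methionine gamma-lyase gene MGL fell by 1.52 ± 0.36 and the cineole synthase gene TPS-CIN fell by 1.48 ± 0.20. OSM34, an osmotin-like gene, fell by 1.45 ± 0.22. With single arrays left out in turn, adjusted p reached 0.141 for MGL (lost in 3 of 4 cases, log2 change between -2.07 and -0.97), 0.0849 for PUB19 (2 of 4), 0.0604 for OSM34 (2 of 4) and 0.0562 for TET12 (1 of 4). With a pseudocount of 1 the log2 change grew to -3.77 for PUB19, -3.55 for TET12, -2.55 for TPS-CIN and -2.38 for MGL.

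**Figure D2:**
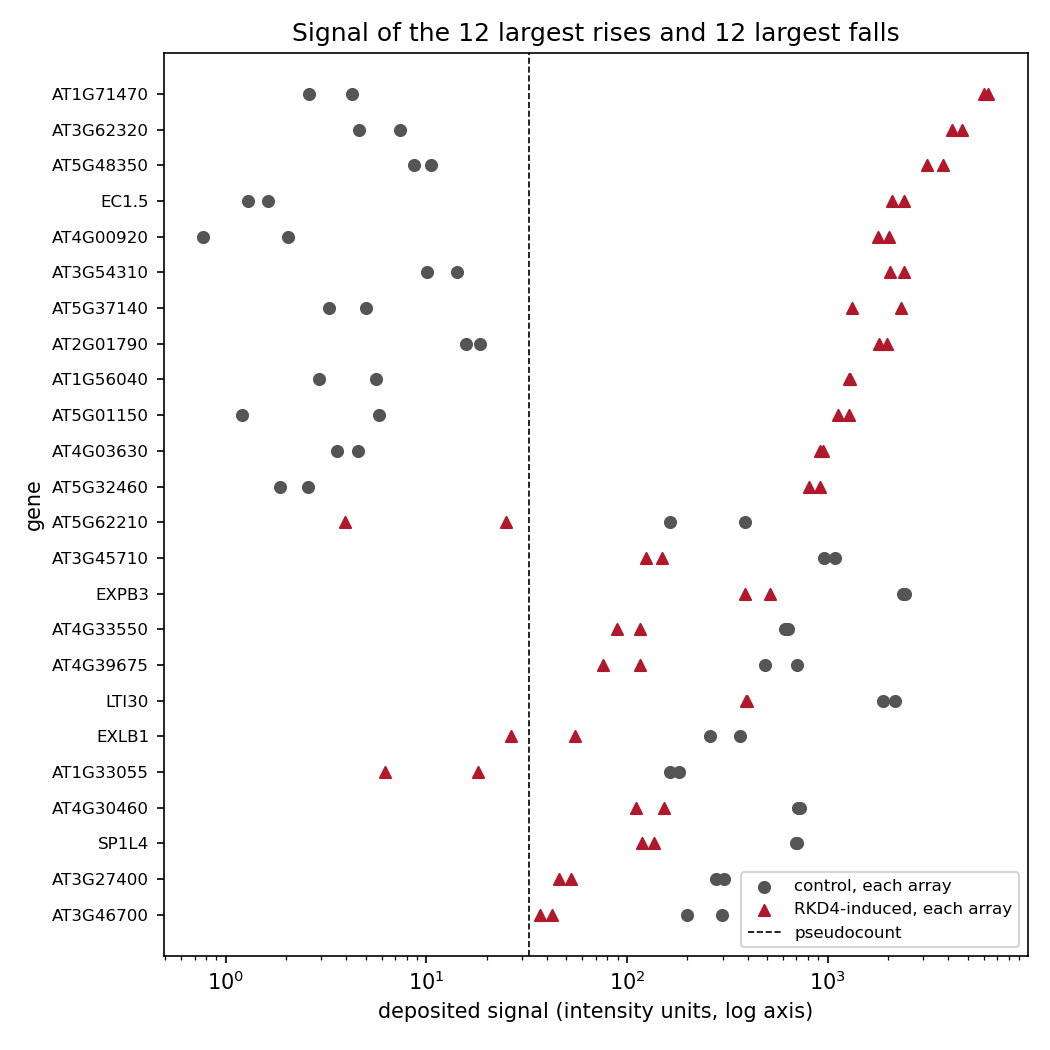
Deposited signal on a log axis (intensity units) of the 12 largest rises and 12 largest falls among probe sets with 1 assigned gene. A grey circle marks each control array, a red triangle each RKD4-induced array and a dashed line the pseudocount of 32.4. In the rises the control arrays sit between 0.772 and 18.5 and the induced arrays between 807 and 6324. All 24 genes were chosen among those whose groups do not overlap.

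Across the array, 4954 of 22746 probe sets passed an adjusted p of 0.05 in limma, of which 2281 rose and 2673 fell. At least 4-fold, 219 rose and 29 fell, and at least 8-fold, 72 rose and 3 fell. Of the 219, 64 had both control signals under the pseudocount. By gene, 1281 rose and 1387 fell. The groups did not overlap in 61.4% of all probe sets, against 33.3% by chance. Between the control arrays 201 probe sets differed over 2-fold, between the induced arrays 57, and between arrays of different groups 1822 to 1939. No probe set was assigned to RKD4 in the table used here, so the induction of RKD4 itself, and with it the labels, could not be checked. Which direction had more calls depended on the setting: median centring gave 2578 higher and 2283 lower. Leaving out control replicate 1 or 2 gave 2223 (1328 higher, 895 lower) or 2144 (1245, 899), and leaving out induced replicate 1 or 2 gave 1835 (1083, 752) or 1907 (1095, 812).

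Gene lists fixed beforehand for embryo, gametophyte, root, leaf and hormone functions could be read only in part, through 38 of 261 genes. Of 5 egg cell genes 2 were measured: EC1.5 rose, and EC1.2 (0.07 ± 0.32) did not pass the test. EC1.2 read between 0.714 and 26.5 on single arrays, all under the pseudocount, so it was near the floor in both groups. In the cytokinin list ARR15 rose, while ARR16, another type-A response regulator, fell by 0.96 ± 0.19. BBM, an AP2-type regulator of embryo and root identity, rose by 0.75 ± 0.21 with an adjusted p of 0.0483, and was the single measured member of the LEC regulator list and also stood in the embryo and root meristem lists. PHV, an HD-ZIP factor of leaf polarity and the other measured embryo patterning gene, fell by 0.48 ± 0.12. JKD, the other root meristem gene, lay at -0.00347 ± 0.19. PAP85, a vicilin-like seed storage protein and the only storage gene measured, fell by 1.05 ± 0.25. Both measured root hair genes fell, EXPA7 by 0.83 and EXPA18 by 0.71 with SE of 0.15 each. Leaving out arrays in turn ended the call in 4 of 4 cases for BBM (adjusted p up to 0.206) and PHV (0.138), and in 3 of 4 for ARR16 (0.100), PAP85 (0.170), EXPA7 (0.0855) and EXPA18 (0.120). Pseudocounts at the 10th percentile (adjusted p 0.0612) and of 1 (0.0679) and the use of 1 probe set per gene (0.0615) ended that of BBM too, though its log2 change was larger with these pseudocounts (1.12 and 1.22) and the same with 1 probe set per gene, and median centring that of PHV (0.0529). With a pseudocount of 1 PAP85 lay at -3.03 and ARR16 at -1.45.

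Few of the measured genes passed in the lists of photosynthesis, auxin, cell division and other functions. Measured were 5 of 21 photosynthesis and 2 of 21 cell division genes. For auxin, 8 of 17 response genes and 3 of 16 synthesis and transport genes were measured. The lists therefore say little on the members without a named probe set. Of 5 photosynthesis genes, PORB, a protochlorophyllide oxidoreductase, fell by 0.54 ± 0.11, and the rest did not pass, among them PSAN (-0.27 ± 0.12), RCA (-0.15 ± 0.17) and LHCB4.1 (-0.13 ± 0.13). Of 8 auxin response genes IAA29 fell by 0.80 ± 0.17, while IAA20 (-0.38 ± 0.22), GH3.5 (-0.34 ± 0.16) and LBD16 (0.33 ± 0.15) did not pass. Of the Aurora kinase genes AUR2 fell by 0.89 ± 0.13 and AUR1 (-0.27 ± 0.17) did not pass. None of 3 auxin synthesis genes passed, YUC2 (-0.38 ± 0.16), YUC6 (0.23 ± 0.29) and YUC4 (0.22 ± 0.27). Likewise none passed of 3 gametophyte and endosperm genes, AGL62 (0.48 ± 0.17), DME (-0.47 ± 0.19) and HTR10 (-0.37 ± 0.28), or of 3 stomatal genes, SPCH (-0.50 ± 0.18), MUTE (-0.23 ± 0.18) and FAMA (-0.18 ± 0.25). Of the genes named so far in this paragraph, IAA20, YUC4, HTR10 and MUTE read under the pseudocount on every array, so their values say little about change. COR15A (-0.56 ± 0.30), the defensin gene PDF1.2 (0.00410 ± 0.21) and the reference genes TIP41 (0.16 ± 0.14) and SAND (-0.11 ± 0.14) did not pass either. The counts were the same adjusted over the list alone. Of 5 lists with at least 3 measured genes none shifted in limma's camera test, with adjusted p between 0.687 and 0.930, or an adjusted p of 0.949 with an estimated correlation. In limma's fry test for change in either direction, which does not compare a list with other genes, the gametophyte and endosperm list (adjusted p 0.00738) and the photosynthesis and auxin response lists (0.00952 each) passed, and the stomatal (0.227) and auxin synthesis (0.367) lists did not. PORB had an adjusted p of 0.0509 in limma without the variance trend. COR15A read above the pseudocount only on control replicate 2 (37.4). With arrays left out in turn, log2 changes lay between -0.84 and -0.77 for IAA29, -0.65 and -0.43 for PORB and -0.95 and -0.84 for AUR2. Each of them lost its call in some or all of these fits, where power is lower. In these cases log2 changes ranged from -1.01 to -0.11 for COR15A, -0.50 to -0.05 for AUR1, -0.65 to -0.12 for IAA20, -0.52 to -0.17 for GH3.5, -0.66 to -0.29 for DME and -0.41 to -0.05 for MUTE.

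Gene families by symbol prefix were grouped after the values were seen, and none was enriched against the other genes with a prefix. A prefix was read from 1539 of the 1557 genes with a symbol, whether or not other genes share it. Of these 1539 genes 12.3% rose and 14.6% fell. Of 47 UGT genes, which encode glycosyltransferases of small molecules, 15 fell, among them UGT84A1, UGT74D1 (fell by 0.98 ± 0.10) and UGT87A2 (fell by 0.95 ± 0.11), and 5 rose, among them UGT74F1 and UGT72E2 (0.84 ± 0.10). Of 9 XTH genes, encoding enzymes that cut and rejoin xyloglucan, 5 fell, with XTH21 the largest (fell by 1.41 ± 0.17, or 4.76 with a pseudocount of 1). Of 10 alpha-expansin genes 5 fell, including EXPA4 (fell by 1.29 ± 0.15), EXPA8 (fell by 1.25 ± 0.15), EXPA15 (fell by 0.76 ± 0.11) and both root hair genes named above. Of 8 CHR chromatin remodelling genes 4 rose, CHR34, CHR40, CHR24 (1.41 ± 0.15) and CHR17 (0.93 ± 0.11). Against those 1539 genes none of 49 families was enriched in Fisher's exact test over 98 tests, with a Benjamini-Hochberg adjusted p of 0.176 for UGT and 0.207 for XTH, EXPA and CHR. Against all named genes, the background tried first, UGT passed with an adjusted p of 0.00483, and XTH (0.0517), EXPA (0.0631) and CHR (0.0842) did not. With an array left out, 5 to 8 UGT, 1 to 2 XTH, 3 to 5 EXPA and 4 CHR genes passed in those directions.

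**Figure D3:**
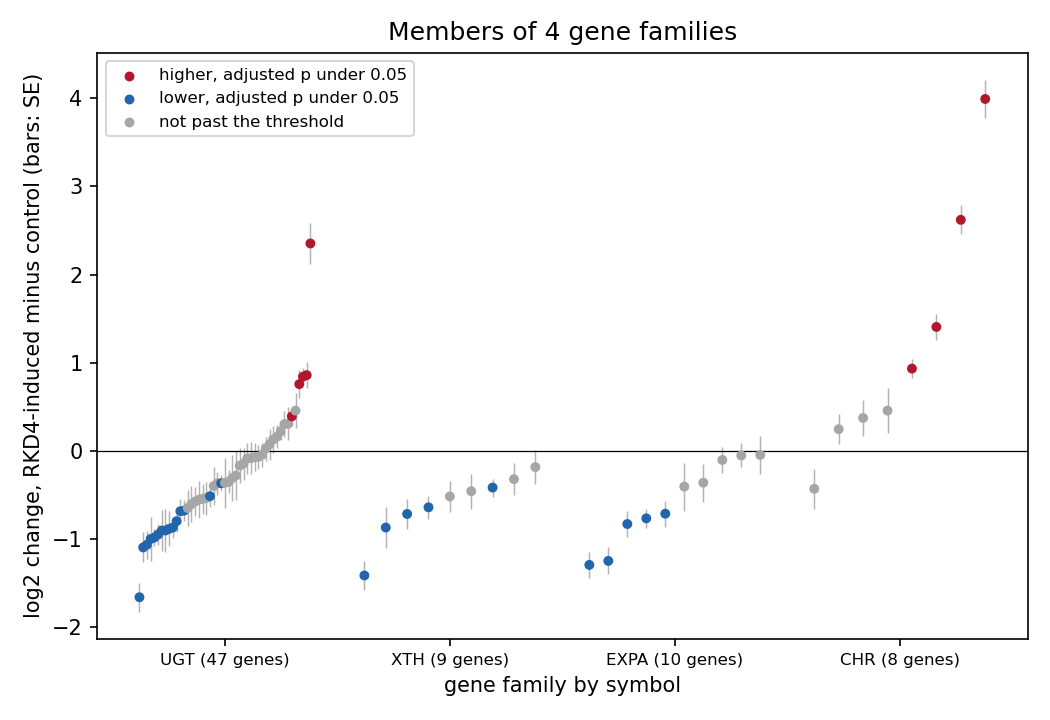
Log2 change of RKD4-induced over control seedlings for each member of 4 gene families, sorted within a family, with bars of 1 SE (n = 2 arrays per group). Red points rose and blue points fell at an adjusted p of 0.05, with 15 of 47 UGT, 5 of 9 XTH and 5 of 10 EXPA genes lower, and 4 of 8 CHR genes higher.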

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

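Alternatives named here as added were chosen after seeing the data, and the rest were fixed before the data were examined. The count of 4954 changed probe sets lay between 4334 (no variance trend) and 6301 (replicate block) under other scalings, pseudocounts, filters and models. Every changed probe set kept its sign with the other scalings and pseudocounts. The filter, the fit without the trend and the replicate block leave each log2 change as it was, so no sign could turn there. The share of rises went from 46.0% to 49.6% with quantile normalization and 53.0% with median centring. An adjusted p under 0.01 gave 2088 (1242 higher, 846 lower), at least 2-fold in addition to 0.05 gave 1593 (980 higher, 613 lower), and at least 2-fold with groups apart and no test gave 1614 (985 higher, 629 lower). With an array left out, 1835 to 2223 passed (1083 to 1328 higher, 752 to 899 lower), where the lone array is assumed to vary like the other group. The added restriction to 1 probe set per gene tests fewer probe sets and gave 2538 (1247 higher, 1291 lower), and the added removal of probe sets that differed between the control arrays gave 5244. The labels do not tell whether same-numbered arrays shared a day or batch, and their deviations correlated at 0.0807, so no pairing was assumed and none was excluded. The replicate block raised the count from 4954 to 6301 and changed no call of a named gene. Of 311 values of the 24 largest changes, 310 kept direction and threshold and 1 lost the threshold. In the settings that leave the log2 change as it was, only the threshold could be lost. No gene list passed a test for a shift in 1 direction (camera or fry) under any setting tried, while 3 of 5 passed fry for change in either direction, which was run in the main setting only. The direction of the auxin synthesis list turned with fry (adjusted p 0.869) and without control replicate 2 (0.559) or induced replicate 1 (0.944). That of the gametophyte and endosperm list turned with the probe set of largest spread (0.970) and without control replicate 1 (0.809) or induced replicate 2 (0.863), and its adjusted p over all 4 such cases lay between 0.559 and 0.944. Among genes that did not pass, EC1.2 lay at -0.20 with a pseudocount of 1, and JKD at 0.0831 with quantile normalization and 0.0461 with median centring. With arrays left out, EC1.2 ranged from -0.35 to 0.48, FAMA from -0.48 to 0.12, HTR10 from -0.78 to 0.0464, JKD from -0.15 to 0.14, PDF1.2 from -0.17 to 0.18, RCA from -0.30 to 0.00439, SAND from -0.27 to 0.0496, TIP41 from -0.000376 to 0.33, YUC4 from -0.14 to 0.59 and YUC6 from -0.17 to 0.64. For all of these the cause was not tested. The alternatives fixed for RKD4 were not run, since it has no named probe set. Weak signal limits the rises, since 29.2% of the 219 probe sets at least 4-fold higher had both control signals under the pseudocount.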

Other observations

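The test of seed proteins in the control pair and all tests of fallen neighbours were chosen after their result was seen, and the families here were grouped after the values were seen. Of 5 beta-tubulin genes TUB1 fell by 1.02 ± 0.13, TUB5 fell by 0.79 ± 0.14 and TUB7 fell by 0.37 ± 0.09, while TUB6 rose by 0.78 ± 0.11 (adjusted p for the falls of the family 0.391, Fisher's exact test). TUB7 lost its call in limma with median centring (adjusted p 0.0615) and without the variance trend (0.0952). With arrays left out, log2 changes lay between -0.39 and -0.35 for TUB7, -0.95 and -0.64 for TUB5 and 0.67 and 0.88 for TUB6. Each lost its call in some or all of these fits, where power is lower. Of 6 LSM genes, which encode RNA-binding subunits of splicing and decay complexes, LSM3B rose by 1.01 ± 0.11, LSM6A by 0.82 ± 0.11 and LSM1A by 0.57 ± 0.15, and LSM1B fell by 0.75 ± 0.15 (adjusted p for the rises 0.391). LSM1A lost its call without the variance trend (adjusted p 0.0759) and with any array left out (up to 0.179), and LSM1B in 3 of 4 cases (0.0982). Of 11 tau class glutathione transferase genes 4 fell, GSTU28, GSTU25 (fell by 1.04 ± 0.10), GSTU18 (fell by 0.64 ± 0.11) and GSTU20 (fell by 0.64 ± 0.17), with an adjusted p of 0.691 for the family. Of 11 RALFL genes, which encode small secreted peptides, 4 fell too, with the same adjusted p. GSTU20 lost its call with median centring (adjusted p 0.0516), without the variance trend (0.0755) and with any array left out (up to 0.187), and GSTU18 in 3 of 4 cases (0.0783). Of 989 pseudogenes tested 11 rose and 16 fell.

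The control pools differed from each other in a lopsided way. Of 201 probe sets that differed over 2-fold, 156 were higher in control replicate 1, or 77.6%, against 28 of 57 in the induced pair. Noise of a single array was not tested apart from this count and stays open. The isocitrate lyase gene ICL, which works in seedlings that use seed oil, read 727 and 78.3, the zinc finger gene STZ 2433 and 409, and the calmodulin-like gene CML23 597 and 145. In the induced pair STZ differed too (692 and 344), while ICL (71.3 and 70.9) and CML23 (154 and 137) differed little. A rapid stress response in control replicate 1 is a candidate explanation. A list of 8 such genes fixed before the test had a median difference of 0.331, at the 99.36 percentile of 10000 lists matched on signal (induced pair 0.140, at 90.74). Of the 8 genes 6 were higher in that pool, while CML42 (-0.18) and CML43 (-0.15) were lower. Seed-stage RNA in that pool may also contribute, since 6 seed protein genes had a median of 0.371 (98.34 percentile) and all 6 were higher there. The induced pair was as extreme the other way (-0.352, 0.83 percentile), so a difference of this list is not particular to the control pair. Both pools belong to the control group, so no biological explanation from the design was tested.

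Genes that fell stood next to each other more often than shuffles gave, where neighbours are genes with no other named and measured gene between them. Among 307 genes that fell at least 2-fold, 16 neighbouring pairs were found. The middle 95% of 10000 shuffles gave 3 to 13, so the 16 lay above what random placement gave there. Since this test was chosen after its result was seen, it cannot exclude random placement at its nominal level. Some pairs share a gene, such as AT5G37990, so they are not all separate places. The same 16 pairs were found without probe sets whose names mark cross-hybridisation, against 2 to 13. That removal kept 304 of the 307 genes and could hardly change the count, so it cannot decide whether cross-hybridisation contributes. Of the same 16 pairs, 10 had no other protein-coding gene of the reference table between them, against 0 to 8 in such shuffles. These 10 included AT3G45700 with AT3G45710 and AT4G30450 with AT4G30460. Tandem copies of a family, which may share regulation or hybridise to each other's probes, were not tested and stay open. Genes that rose at least 2-fold showed no such excess, with 30 pairs against 16 to 35 in the shuffles, and 16 against 6 to 20 by the stricter definition.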
